A study of Mus musculus with 11 samples.

How the data were processed

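RNA of pooled mouse hearts at embryonic day 9.5 was measured on 11 one-colour oligonucleotide arrays, 1 array per sample. Total RNA had been extracted with TRIzol, and 50 ng of it was amplified and turned into biotin-labelled cDNA with an Ovation kit, per the labels' protocols. The deposited values are linear intensities, 1 summary value per probe set and array, with 45101 probe sets per array and none below 0. PLIER, a method that summarises the probes of a probe set into 1 value, is the only tool named in the submitters' processing notes. The background correction, the scaling between arrays and the PLIER version used by the authors are not given in the sources used here, nor are detection calls, so no probe set could be called present or absent. Mean deposited intensity lay between 166.4 and 175.6 in 10 arrays and was 117.2 in CKO replicate 3.

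Arrays were placed in 3 groups from the genotype in their labels: 3 control, 3 double heterozygous and 5 conditional knockout (CKO) arrays. All array columns of the table were used. The labels number the replicates but name no litter, day or batch. No 2 arrays shared more than 0.829% identical values, and Pearson correlations between arrays over probe sets ranged from 0.954 to 0.990, so no array was treated as a copy of another.

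From the deposited intensities, log2(value + 16) was computed. An offset of 16 shrinks the fold changes of dim genes, so all fold changes are on the log2(value + 16) scale and understate changes at low intensity. The array medians on this scale spanned 0.465, more than the limit of 0.2 set beforehand, and the arrays were therefore quantile normalised, which also forces all arrays to 1 distribution. The 64 control probe sets were left out, which left 45037 probe sets in every test, with no filter on intensity. A linear model with 1 coefficient per genotype group was fitted to all 11 arrays with limma 3.58.1 in R 4.3.3, followed by empirical Bayes moderation with an intensity trend (8 residual degrees of freedom, 15.07 after moderation). The contrasts were CKO minus control, CKO minus double heterozygous, double heterozygous minus control, and double heterozygous minus the mean of the other groups, together with an F-test over the 3 groups, which is the counterpart of the one-way analysis named in the series description. All tests were two-sided except Fisher's exact test of chromosome neighbours in the closing section. P-values were adjusted by Benjamini-Hochberg within each contrast, and a probe set was called at an adjusted p under 0.05.

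Gene symbols came from a table of the platform's annotation, in which 34945 of the tested probe sets had 1 symbol, 932 had several and 9160 had none. Through their Entrez identifiers 34741 of these symbols matched a RefSeq gene table (GRCm38.p6), and 0 symbols changed. No coordinates are given, because the sources used here name no genome build for the array. Probe sets with several symbols were not named. Each of the 18193 genes was represented by its probe set with the highest mean, passing over _x_at and _s_at probe sets where another existed.

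There were 27 gene lists, for cell cycle, heart, signalling, stress and cell types of a dissected heart region. They held 403 distinct genes, some of them in more than 1 list, so the lists are not all separate. The lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined, except where a choice is said to come later. Of the 403 genes, 383 matched a probe set with 1 symbol. Those not matched included Ccnb1, Hcn4, Gapdh and Ddx3y. Lists were tested with camera (preset correlation 0.01), with camera with an estimated correlation and with fry, and adjusted over 81 tests (27 lists in 3 comparisons). A list member was counted as called on the probe set that represents its gene, with p-values adjusted over all probe sets. It was counted again with p-values adjusted over the list alone. A member not called can thus have another probe set that was called. A list score is the mean, over the members, of the log2 difference from the control mean.

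The rule named, for each pairwise comparison, Gata4, Nkx2-5 and Ccnd2. It then named the 8 called genes with the largest rise and the 8 with the largest fall among those whose groups of arrays did not overlap, or the 3 with the smallest p in each direction where none was called. From each list with a called shift or a called member it took up to 4 members with the smallest p, and up to 2 from other lists. Clone-like names were passed over. Genes outside this rule are said to be so where they appear.

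In simulated arrays with 200 changed probe sets among 45037, the fit recovered 20.9% of changes of 0.5, 73.1% of changes of 1 and 89.4% of changes of 1.5 on the log2 scale for CKO against control. The same sizes were recovered at 16.4%, 74.6% and 95.5% for CKO against double heterozygous arrays, and at 17.9%, 70.1% and 87.9% for double heterozygous against control arrays. Of the probe sets called in these 3 simulations, 6.15%, 3.12% and 4.1% were unchanged ones. With no change simulated, 0 probe sets were called in each contrast. The simulated noise was independent between probe sets and had the same SD in all arrays. The real CKO arrays were less alike than the others, so these rates may not hold for the real data. Alternatives varied the offset (1 and 64), the scaling (as deposited, or median centring), a filter on the dimmest 40% or 60% of probe sets, the variance model, array weights, the probe set rule, the replicate number as a block, the arrays in the fit (only the groups compared, or without each array in turn) and the list test. Chosen after seeing the data were a fit without CKO replicates 2 and 3 and a fit with the beta-actin 3' to 5' difference as a covariate. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.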

Results

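Expression was measured in pooled mouse hearts at embryonic day 9.5 that carried floxed alleles of Gata4, which encodes a zinc-finger transcription factor of the early heart, and Cre recombinase inserted at Nkx2-5, a homeobox gene of cardiac progenitors and myocardium. Control hearts had 1 floxed Gata4 allele and no Cre (n = 3 arrays). Double heterozygous hearts had 1 floxed Gata4 allele and 1 Nkx2-5 Cre allele (n = 3). Conditional knockout (CKO) hearts had 2 floxed Gata4 alleles and 1 Nkx2-5 Cre allele (n = 5). The series title places the question in cell proliferation of the second heart field-derived myocardium and in the cell cycle gene Ccnd2, which encodes cyclin D2. The number of arrays limits the precision. The labels describe pooled hearts without saying that replicates came from separate pools or litters, so p-values measure only the spread between these samples, which may be technical.

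The arrays of the CKO group were less alike than those of the other groups. CKO replicate 2 had a beta-actin 3' to 5' difference of 1.0 on the log2 scale against 0.295 to 0.45 in the 10 other arrays. CKO replicate 3 had a mean deposited intensity of 117.2 against 166.4 to 175.6. Their mean correlations with the other CKO arrays were 0.967 and 0.965, below the 0.977 to 0.988 of the other arrays with their own groups. The first 2 principal components held 22.8% and 20.8% of the variance, with CKO replicate 2 at one end of the first (59.6) and CKO replicate 3 at one end of the second (-70.2).

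Gata4 transcript signal was not lower in the arrays labelled CKO. The brighter of its 2 probe sets averaged 8.98 ± 0.18 in control arrays (SD, n = 3), 9.31 ± 0.097 in double heterozygous arrays (n = 3) and 9.43 ± 0.11 in CKO-labelled arrays (n = 5), on the log2 scale. It was 1.37-fold higher in CKO-labelled than in control arrays (log2 fold change 0.45, SE 0.097, adjusted p = 0.0321, limma). The call was lost in 13 of 26 alternatives, among them the deposited scale (0.30) and median centring (0.29). Of the single arrays, it was lost without control replicate 1 (0.34), 2 (0.51) or 3 (0.50), double heterozygous replicate 1 (0.45) or 3 (0.45), or CKO replicate 5 (0.43). The dimmer probe set differed by 0.08 (SE 0.38), with CKO replicate 2 at 6.42 and the 4 other CKO-labelled arrays between 8.26 and 8.81. Whether either probe set lies within the deleted part of the gene is not given in the sources used here, so Gata4 signal does not check the labels, and these arrays are called CKO-labelled throughout. Nkx2-5 signal was 9.87 ± 0.056 in control, 9.48 ± 0.097 in double heterozygous and 9.34 ± 0.34 in CKO-labelled arrays, and all 8 arrays with Cre lay below all 3 control arrays. Neither difference from control passed the test (log2 fold change -0.53, adjusted p = 0.0990, for CKO-labelled arrays, and -0.39, adjusted p = 1, for double heterozygous arrays).

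The comparison of CKO-labelled with control arrays asks what differs with 2 floxed Gata4 alleles and Cre against 1 floxed allele without Cre. Ccnd2, the D-type cyclin that drives cells from G1 into S phase, was 1.39-fold lower in CKO-labelled arrays. Its brightest probe set averaged 11.15 ± 0.19 (SD, n = 5) against 11.62 ± 0.041 in control arrays (n = 3), a log2 fold change of -0.48 (SE 0.093, adjusted p = 0.0197). All 7 Ccnd2 probe sets had lower means in CKO-labelled arrays, and 3 of them were called, with log2 fold changes of -0.48, -0.46 and -0.39. CKO replicate 2 read 11.48 on the brightest, near the control arrays at 11.59 to 11.67, while the 4 other CKO-labelled arrays lay between 11.03 and 11.14. On the Ccnd2 probe set with the smallest adjusted p all 5 CKO-labelled arrays, from 10.65 to 10.88, lay below the 3 control arrays at 11.22 (log2 fold change -0.46, SE 0.073, adjusted p = 0.00497). The call of the brightest Ccnd2 probe set was lost in 9 of 26 alternatives, among them the deposited scale, and of the single arrays without control replicate 1 (-0.49), control replicate 2 (-0.49), control replicate 3 (-0.46) or CKO replicate 5 (-0.45).

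**Figure D1:**
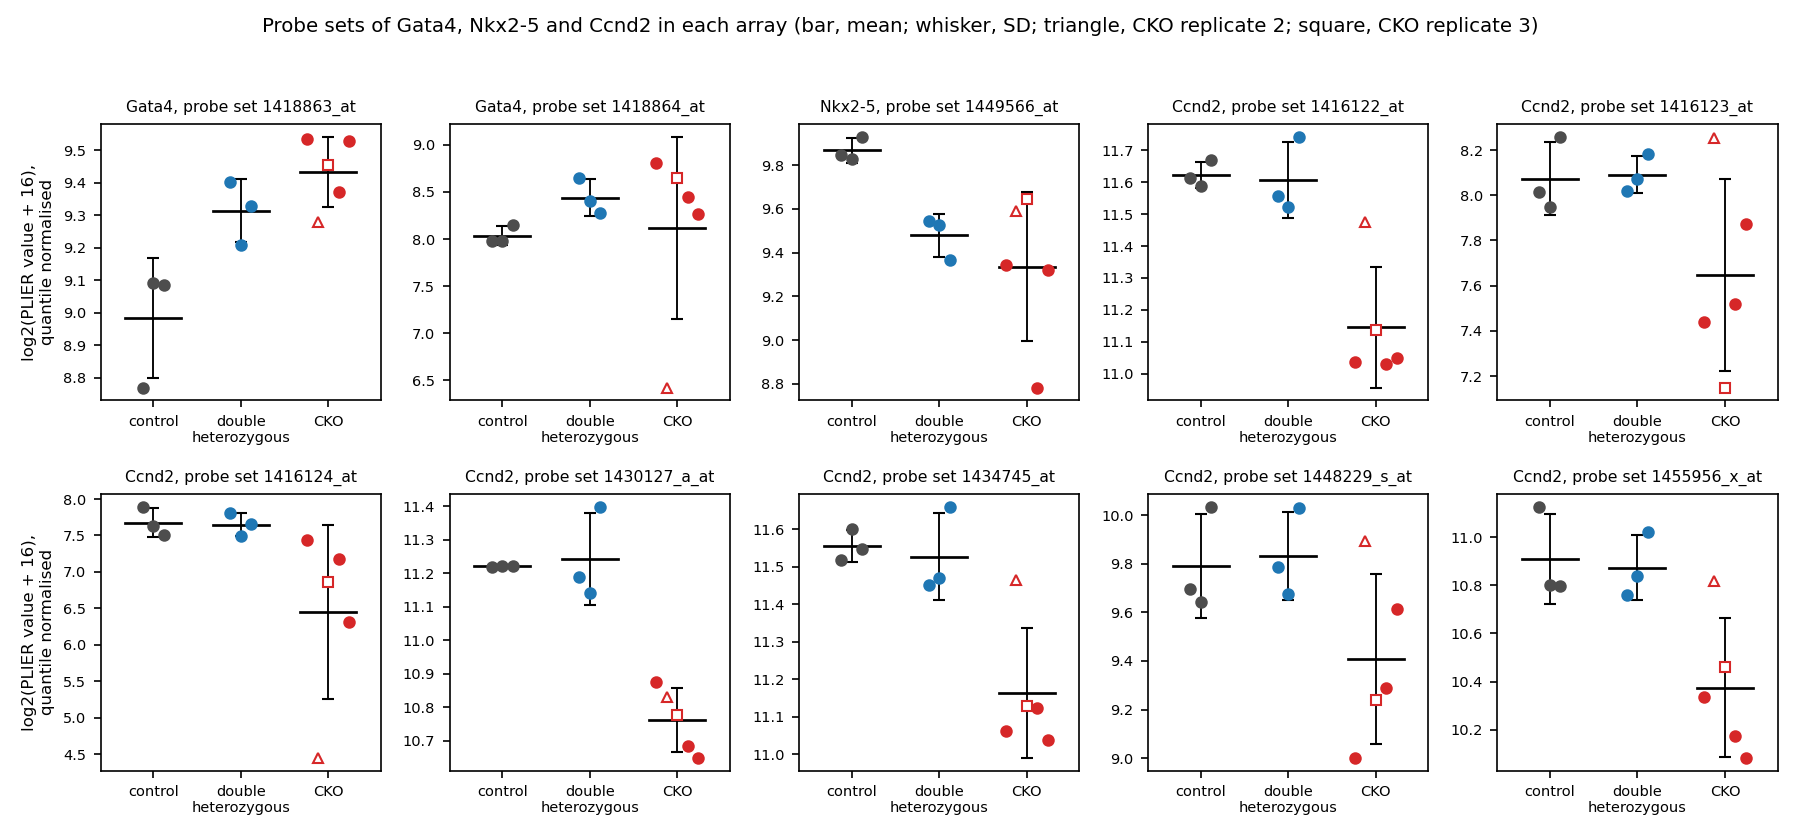
Level of each probe set of Gata4, Nkx2-5 and Ccnd2 in the 11 arrays, as log2(PLIER value + 16) after quantile normalisation, with 1 point per array, the group mean as a bar and the SD as a whisker; y axes differ between panels and do not start at 0. All 7 Ccnd2 panels have a lower mean in CKO-labelled arrays than in control arrays, and CKO replicate 2 (triangle) lies near the control level in several of them, with 11.48 on the brightest.

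Across the array, 632 of 45037 probe sets were called between CKO-labelled and control arrays, 377 higher and 255 lower, on 471 named genes. The largest rises among genes whose groups did not overlap were those of Igfbp3, which encodes a binding protein of insulin-like growth factors (4.47-fold, log2 fold change 2.16, SE 0.20, adjusted p = 8.39e-05), Sparcl1, a secreted matrix-associated protein (3.84-fold), and Ier3, a stress-inducible gene (3.79-fold). They were followed by Ddit4, an inhibitor of the growth-promoting kinase complex mTORC1 (3.39-fold), Vldlr, a lipoprotein receptor (3.14-fold), Krt19, a keratin of simple epithelia (3.00-fold), Egln3, an oxygen-sensing prolyl hydroxylase (2.92-fold), and Clec14a, an endothelial C-type lectin (2.73-fold). The largest falls were those of Itga4, the alpha 4 integrin subunit (log2 fold change -1.96, SE 0.25, adjusted p = 0.000870), Mlip, a muscle protein that binds lamin A (-1.81), and Aldh1a1, a retinaldehyde dehydrogenase (-1.78). Next came Aqp4, a water channel (-1.43), Tcf21, a transcription factor of the proepicardium (-1.31), Lrrn4, a gene of mesothelial cells (-1.20), Slitrk5, a membrane protein best known from neurons (-1.19), and Aldh1b1, a mitochondrial aldehyde dehydrogenase (-1.04). Aldh1a1 lay near the level of a deposited value of 0 in 4 CKO-labelled arrays, so its log2 fold change depends on the offset (-4.19 with an offset of 1 and -0.77 with 64). With an offset of 64 the log2 fold change was 1.09 for Vldlr, -0.79 for Aqp4, -0.74 for Slitrk5 and -0.59 for Aldh1b1. As the mean of a gene's probe sets it was -1.06 for Itga4, -0.85 for Mlip, -0.94 for Aqp4 and -0.72 for Tcf21. Of 26 alternatives the call was lost in 4 for Tcf21 and 3 for Lrrn4. Each of these 16 genes separated all 5 CKO-labelled from all 3 control arrays, because the naming rule required it. For Mlip 1 of 2 probe sets was lower, and for the other 15 genes all probe sets with that symbol moved the same way. Of 18193 genes, 12.1% had groups that did not overlap, where chance gives 3.57% for 3 against 5 arrays.

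Of the cell cycle lists, DNA replication genes were lower in CKO-labelled arrays. All 23 measured members had lower means (mean log2 fold change -0.36, median -0.35), 3 were called over all probe sets and 21 when adjusted over the list alone. All 5 CKO-labelled arrays scored below all 3 control arrays (camera adjusted p = 3.25e-14, and adjusted p = 0.0326 with an estimated correlation). The called members were Pcna, the sliding clamp of DNA polymerase (log2 fold change -0.38, SE 0.072), Gins1, a subunit of the replicative helicase (-0.49, SE 0.11), and Mcm7, another helicase subunit (-0.40, SE 0.094). These calls were lost in 8, 14 and 19 of 26 alternatives, that of Mcm7 with both other offsets, with both other scalings and as the mean of its probe sets (-0.25). Gins2, at -0.49, did not pass (adjusted p = 0.0585). Of 24 genes for G2, M phase and mitosis, 23 had lower means (mean -0.27), 2 were called and 19 passed when adjusted over the list alone (camera adjusted p = 1.31e-12, and adjusted p = 0.0561 with an estimated correlation). Kif20a, a kinesin of cytokinesis (-0.61, SE 0.11, adjusted p = 0.0124), and Cdk1, the mitotic kinase (-0.27, SE 0.063, adjusted p = 0.0493), were called, and Ccnb2 (-0.31) and Kif23 (-0.39) were not. The call of Kif20a was lost in 8 and that of Cdk1 in 17 of 26 alternatives, although Cdk1 was lower still on the deposited scale (-0.44) and with median centring (-0.45), as was the list (-0.42 on each). In the list of G1-S regulators 2 of 17 members fell, Ccnd2 and the proto-oncogene Mycn (-0.42, SE 0.090, adjusted p = 0.0300), both also when adjusted over the list alone. For Mycn 2 of 3 probe sets were lower, and its call was lost in 11 of 26 alternatives, among them the deposited scale and the mean of its probe sets (-0.16). Cdk4 and Cdk2 did not pass (-0.20 and -0.19). That list's mean was -0.12 (camera adjusted p = 0.0291, and adjusted p = 0.113 with an estimated correlation). Its call was lost without control replicate 2 (-0.11), CKO replicate 1 (-0.12) or CKO replicate 3 (-0.10), and the mean was -0.25 on the deposited scale and -0.26 with median centring. Among 8 CDK inhibitors 0 were called (mean 0.14), and the list did not pass with camera (adjusted p = 0.134, and adjusted p = 0.313 with an estimated correlation). It passed with fry, which does not compare a list with other genes (adjusted p = 0.0461), and all 5 CKO-labelled arrays scored above all control arrays. Of its members, Cdkn2b was at 0.27 and Cdkn1c at 0.10 (a value whose sign changed on the deposited scale and with median centring). Cdkn2b was dim (4.724 to 4.759 in control and 4.645 to 5.673 in CKO-labelled arrays, highest in CKO replicate 3), so its value depends on the offset. Among 14 genes of p53 response and apoptosis 0 were called (mean -0.12, camera adjusted p = 0.152), with Ccng1 at -0.31 and Perp at -0.47.

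Hypoxia and glycolysis genes rose together in CKO-labelled arrays. All 18 measured members had higher means (mean log2 fold change 0.63, median 0.60), 11 were called and 15 passed when adjusted over the list alone. The 5 CKO-labelled arrays scored between 0.41 and 0.84 while the 3 control arrays scored between -0.028 and 0.054 (camera adjusted p = 1.18e-19, and adjusted p = 0.0471 with an estimated correlation). Besides Ddit4 and Egln3, the called genes included Bnip3, a mitophagy receptor induced by low oxygen (0.79, SE 0.096, adjusted p = 0.000566), and Higd1a, a hypoxia-induced mitochondrial protein (0.50, SE 0.079, adjusted p = 0.00457). Vegfa, the endothelial growth factor (0.91, adjusted p = 0.0451), Hk2, a hexokinase (0.75), and Slc2a1, a glucose transporter (0.36), were also called, and were chosen for naming after their values were seen. The call of Vegfa was lost in 15 of 26 alternatives, and the calls of Vegfa, Higd1a, Hk2 and Slc2a1 were lost on the deposited scale and with median centring (0.33 for Higd1a and 0.24 for Slc2a1 with the latter) and that of Bnip3 on the deposited scale. Of 20 genes of oxidative metabolism 18 had lower means (mean -0.20, camera adjusted p = 1.49e-06, and adjusted p = 0.0492 with an estimated correlation). Acadm, a dehydrogenase of fatty acid oxidation, was the 1 called member (-0.35, SE 0.078, adjusted p = 0.0387), and 9 passed when adjusted over the list alone. Its call was lost in 12 of 26 alternatives, both other scalings among them, while the list mean was -0.35 on each of these scalings. Ndufs1 (-0.40), Cs (-0.23) and Cox5a (-0.22) did not pass over all probe sets. The erythroid list, whose cells the pools could hold in differing amounts, had a mean of 0.21 with 0 of 12 members called (camera adjusted p = 0.0357, and adjusted p = 0.629 with an estimated correlation). Of the CKO-labelled arrays 2 of 5 arrays scored above all control arrays. That call was lost with fry (adjusted p = 0.574), on the deposited scale (0.12), with median centring (0.11), and without control replicate 3 (0.097), CKO replicate 1 (0.12) or CKO replicate 4 (0.13), and the mean was 0.37 without CKO replicates 2 and 3 together. Alas2 was at 0.52, Slc4a1 at 0.46, Gata1 at 0.24 and Rhag at 0.35. Immediate early and heat shock genes had a mean of 0.20 (camera adjusted p = 0.0862), with Fos called (0.88, SE 0.19, adjusted p = 0.0356) and Hsph1 (-0.30), Dusp1 (0.48) and Jun (0.20) not. The Fos call was lost in 13 of 26 alternatives, both other scalings among them. Genes of unfolded protein and amino acid stress had 0 of 12 called on the probe sets that represent them (mean 0.11, camera adjusted p = 0.364), with Chac1 at 0.80 and Trib3 at 0.37. The mean of this last list changed sign with median centring.

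Among cardiac genes, members of single lists moved in both directions. Of 21 cardiac transcription factors, Gata4, Gata5 (0.43, named after its value was seen) and Gata6 (0.41, SE 0.077, adjusted p = 0.0142) were called higher. Hopx, an atypical homeodomain protein (-0.55, SE 0.089, adjusted p = 0.00585), and Irx4, a ventricular homeobox gene (-0.62, SE 0.12, adjusted p = 0.0165), were called lower (6 higher and 4 lower when adjusted over the list alone). The calls were lost in 16 of 26 alternatives for Gata5 and in 8 each for Gata6 and Irx4, on the deposited scale for all 3 genes (0.29 for Gata5 and 0.26 for Gata6) and with median centring for Gata5 (0.28) and Gata6 (0.26). Isl1, the LIM-homeodomain factor of second heart field progenitors, was 2.60-fold higher (log2 fold change 1.38, SE 0.13, adjusted p = 8.39e-05). On the probe sets that represent the genes, Isl1 was the 1 called member of its list of 19 genes. The list had a mean of 0.23 (median 0.09), 7 members passed when adjusted over the list alone, and 4 of 5 CKO-labelled arrays scored above all control arrays (camera adjusted p = 8.85e-05, and adjusted p = 0.166 with an estimated correlation). The list mean was 0.14 on the deposited scale and 0.13 with median centring. Rgs5 was at 0.62, Plxna2 at 0.51 and Wnt5a at 0.32. Among 24 sarcomere genes Acta1, skeletal alpha-actin (0.44, SE 0.055, adjusted p = 0.000638), Myh7, beta myosin heavy chain (0.27, SE 0.051, adjusted p = 0.0154), and Ldb3, a Z-disc protein (0.27, SE 0.063, adjusted p = 0.0468), were higher. Tnni3, cardiac troponin I (-0.66, SE 0.13, adjusted p = 0.0266), was lower (5 and 5 when adjusted over the list alone). The calls of Acta1, Myh7 and Ldb3 were all lost on the deposited scale and with median centring, where Myh7 was at 0.17 and 0.16 and Ldb3 at 0.10 and 0.093. Over all 26 alternatives the call was lost in 8 each for Myh7 and Tnni3 and in 16 for Ldb3, among them the mean of its probe sets and each fit without 1 control or double heterozygous array. Of 16 chamber and trabecular genes, Fhl2, a LIM-domain protein of heart muscle (-0.79, SE 0.11, adjusted p = 0.00218), and Irx4 fell, while Smpx (-0.34) and Tgfb2 (0.41) did not pass. Of 16 described GATA4 target genes, Ccnd2 and Tnni3 fell, and Nkx2-5 and Bmp4 (0.36) did not pass. The camera adjusted p was 0.301 for cardiac transcription factors, 0.227 for sarcomere genes, 0.907 for chamber genes and 0.923 for described GATA4 targets. It was 0.195 for 16 genes of calcium handling, ion channels and gap junctions, with 0 called on the probe sets that represent them (Ryr2 at 0.26, Gja1 at 0.38). The means of the transcription factor, sarcomere and calcium handling lists, at 0.03, 0.05 and 0.06, changed sign on the deposited scale and with median centring. The chamber and GATA4 target lists had negative means (-0.03 and -0.03) but positive medians (0.02 and 0.05). BMP signalling genes had 5 of 14 called, all higher, with 6 passing when adjusted over the list alone (mean 0.20, camera adjusted p = 2.11e-04, and adjusted p = 0.0569 with an estimated correlation). They were Smad7, an inhibitory SMAD (0.82, SE 0.15), Bambi, a decoy receptor (0.38, SE 0.074), the ligands Bmp5 (0.52, SE 0.11) and Bmp7 (0.46, named after its value was seen), and Id1, a direct BMP response gene (0.41, SE 0.086). All 5 of these calls were lost on the deposited scale and with median centring (0.22 and 0.21 for Bambi, 0.27 and 0.26 for Id1), as was the BMP list's on the deposited scale (0.078, and 0.070 with median centring). They were lost in 6 of 26 alternatives for Smad7, 7 for Bambi, 10 for Bmp5, 11 for Id1 and 18 for Bmp7, which was at 0.20 as the mean of its probe sets and also lost its call with both other offsets.

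Markers of other cell types also moved. Endothelial and endocardial genes were higher in CKO-labelled arrays (mean log2 fold change 0.27), with 16 of 18 means higher, 3 called higher and 1 lower, and 8 higher and 1 lower when adjusted over the list alone. All 5 CKO-labelled arrays scored above all control arrays (camera adjusted p = 3.58e-06, and adjusted p = 0.0343 with an estimated correlation). Flt1 and Kdr, the VEGF receptors 1 and 2, rose (0.98, SE 0.15, and 0.69, SE 0.12), as did Cdh5, VE-cadherin (0.63, SE 0.12), and Tek, the angiopoietin receptor, fell (-0.65, SE 0.088, adjusted p = 0.00150). The calls of Flt1, Kdr and Cdh5 were lost on the deposited scale, and in 3, 5 and 11 of 26 alternatives, with Flt1 at 0.58 and Cdh5 at 0.36 as the mean of their probe sets. The list mean was 0.14 on the deposited scale and with median centring. Proepicardial and epicardial genes had 4 of 12 members called lower and Krt19 called higher (mean -0.63, median -0.89, 7 lower when adjusted over the list alone). All 5 CKO-labelled arrays scored below all control arrays (camera adjusted p = 2.66e-04, and adjusted p = 0.342 with an estimated correlation). Besides Aldh1a1, Tcf21 and Lrrn4, the fourth lower gene was Upk1b, a uroplakin of mesothelium (-1.0, SE 0.19, adjusted p = 0.0151), whose call was lost in 5 of 26 alternatives (-0.62 with an offset of 64). The list was not called with fry (adjusted p = 0.172), and its mean was -1.01 with an offset of 1 and -0.34 with 64. Of 18 genes of cushion mesenchyme and matrix, Col2a1, type II collagen (-0.83, SE 0.099), Hapln1, a hyaluronan link protein (-0.71, SE 0.086), and Cthrc1 (-0.70, SE 0.15) fell and Vcan, the proteoglycan versican, rose (0.43, SE 0.066). For Vcan 7 of 8 probe sets were higher, and its call was lost in 4 of 26 alternatives, among them the deposited scale (0.28) and median centring (0.27), and that of Cthrc1 in 7 (-0.41 with an offset of 64). The list mean was -0.22 (camera adjusted p = 0.0167, and adjusted p = 0.428 with an estimated correlation), and 3 members were higher and 10 lower when adjusted over the list alone. This list's call was lost without control replicate 3 (-0.18), CKO replicate 1 (-0.19) or CKO replicate 2 (-0.17), without CKO replicates 2 and 3 together (-0.12) and with fry (adjusted p = 0.0893), and its mean was -0.34 with median centring. In the list of pharyngeal and foregut endoderm 3 of 14 genes rose, the simple-epithelial keratins Krt18 (0.85, SE 0.11) and Krt8 (0.71, SE 0.10) and Sox17, a transcription factor also of endothelium (0.92, SE 0.14). Pax9 was at -0.33 (mean 0.21, camera adjusted p = 0.00601, adjusted p = 0.351 with an estimated correlation and 0.231 with fry). The calls of all 3 genes were lost on the deposited scale and that of Krt8 also with median centring, Sox17 was at 0.53 with an offset of 64, and the list mean was 0.47 without the dimmest 40% of probe sets and 0.83 without the dimmest 60%. The smooth muscle list had a mean of 0.22 and 1 of 8 genes called, Tagln, an actin-binding protein (0.30, SE 0.069, adjusted p = 0.0479). The call of Tagln was lost in 18 of 26 alternatives, and both it and the call of the list were lost on the deposited scale (0.16 for Tagln and 0.12 for the list) and with median centring (0.15 and 0.11). Myocd was at 0.44, Lmod1 at 0.49 and Acta2 at 0.23 (camera adjusted p = 0.0191 for the list, and adjusted p = 0.115 with an estimated correlation). The probe set that represents Acta2 was dim, at 5.275 to 5.732 over all arrays, so its value says little about smooth muscle. No member was called in the platelet and myeloid (mean -0.05, camera adjusted p = 0.949), liver bud (0.04, 0.511), neural crest (0.19, 0.144), neural tube (0.01, 0.757) and sex-linked (0.28, 0.222) lists. The sex-linked list pools Xist with Y chromosome genes, which go opposite ways with the sex makeup of a pool. Its mean therefore cannot test sex makeup in any comparison. Single arrays differed, with Xist from 8.035 to 9.945 and Eif2s3y, a Y chromosome gene, from 6.63 to 8.073. The sign of the neural tube mean changed on the deposited scale and with median centring.

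The count of 632 probe sets depended on the arrays and the scaling. It was 168, 181 or 187 without control replicate 1, 2 or 3, 361 without double heterozygous replicate 1, 282 without CKO replicate 5 and 1362 without CKO replicates 2 and 3 together. The share of calls that were higher was 59.7%, against 48.9% of 92 on the deposited scale and 39.2% of 362 with median centring. Of 59 called genes named for this comparison, 28 kept their call without any 1 of the 11 arrays, among them Igfbp3, Sparcl1, Krt19, Itga4, Mlip and Isl1. The call was lost for 29 genes without control replicate 1, 2 or 3, for 14, 9 or 11 without double heterozygous replicate 1, 2 or 3, and for 5, 3, 3, 4 or 16 without CKO replicate 1, 2, 3, 4 or 5.

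**Figure D2:**
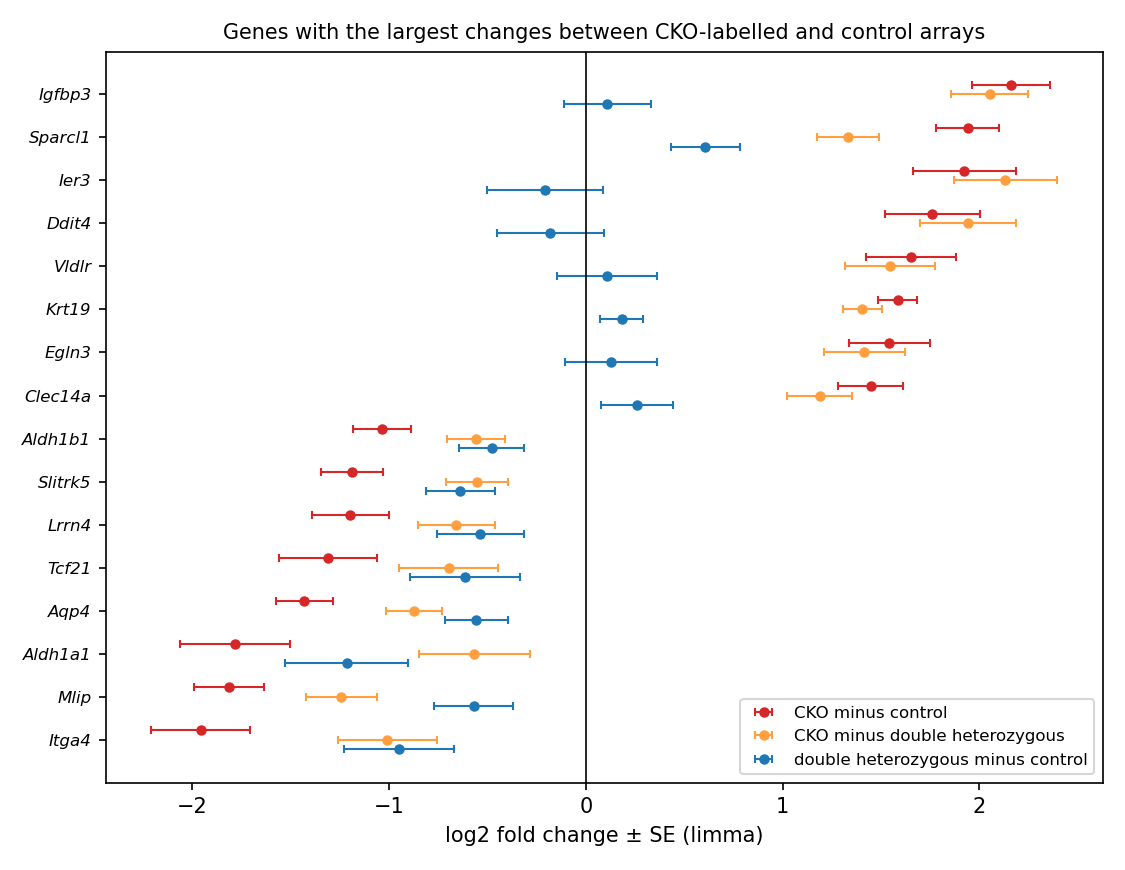
Log2 fold changes with SE (limma) of the 16 genes with the largest rises and falls between CKO-labelled (n = 5) and control arrays (n = 3), for the 3 pairwise comparisons. Igfbp3 and Ier3 differ by about the same amount from both other groups (2.16 and 2.05, and 1.92 and 2.13), while the mean of double heterozygous arrays lies between the other means for Aldh1a1 (-1.22 from control) and Itga4, with CKO replicate 4 inside the double heterozygous range for Itga4 and above it for Aldh1a1.

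The comparison of CKO-labelled with double heterozygous arrays asks what differs with the second floxed Gata4 allele when both groups carry Cre at Nkx2-5. Ccnd2 was 1.38-fold lower in CKO-labelled arrays on its brightest probe set (log2 fold change -0.46, SE 0.093, adjusted p = 0.0497). The levels were 11.15 ± 0.19 (SD, n = 5) and 11.61 ± 0.12 (n = 3). Of the Ccnd2 probe sets 2 of 7 probe sets were called, all 7 with lower means. This call, near the threshold, was lost in 17 of 26 alternatives. Of the single arrays, it was lost without control replicate 1 (-0.46), 2 (-0.46) or 3 (-0.46), double heterozygous replicate 1 (-0.49), 2 (-0.51) or 3 (-0.39), or CKO replicate 1 (-0.43), 4 (-0.43) or 5 (-0.43). The Ccnd2 probe set with the smallest adjusted p gave -0.48 (SE 0.073, adjusted p = 0.00894). Gata4 differed by 0.12 (SE 0.097, adjusted p = 0.668), a value whose sign changed on the deposited scale and with median centring, and Nkx2-5 by -0.14 (SE 0.15, adjusted p = 0.747).

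In this comparison 157 probe sets were called, 129 higher and 28 lower, on 124 named genes. The largest rises were those of Ier3 (4.38-fold, log2 fold change 2.13, SE 0.26, adjusted p = 0.00265), Igfbp3 (4.15-fold), Ddit4 (3.85-fold), Vldlr (2.92-fold), Egln3 (2.67-fold), Krt19 (2.65-fold), Stc1, a secreted glycoprotein hormone (2.59-fold), and Sparcl1 (2.52-fold). The largest falls were those of Mlip (-1.24, SE 0.18, adjusted p = 0.00695), Agtr1a, an angiotensin II receptor (-0.89), Aqp4 (-0.87), Rpp25, a subunit of ribonuclease P (-0.76), Iqgap2, a scaffold protein (-0.74), Frmd5 (-0.71), Lemd1 and Ppp1r14c, an inhibitor subunit for protein phosphatase 1 (-0.62). Lemd1 lay at 4.0, the level of a deposited value of 0, in 3 CKO-labelled arrays and at 4.056 and 4.257 in the others, so its log2 fold change is set by the offset (-3.02 with an offset of 1 and -0.21 with 64), and its call (adjusted p = 0.0494) was lost in 20 of 24 alternatives. The call was lost in 16 of 25 alternatives for Rpp25, 8 of 25 for Agtr1a and 6 of 25 for Aqp4, and of 26 alternatives in 13 for Ppp1r14c, 12 for Iqgap2, 8 for Frmd5 and 5 for Vldlr. The offset moved Agtr1a (-1.34 with 1 and -0.44 with 64) and Rpp25 (-1.20 and -0.36), and as the mean of a gene's probe sets Mlip was at -0.58, Aqp4 at -0.57 and Stc1 at 0.86. All 16 genes separated the 5 CKO-labelled from the 3 double heterozygous arrays, because the naming rule required it, and 1 of 2 Mlip probe sets was lower. Of 31 called genes named for this comparison, 5 kept their call without any 1 of the 11 arrays: Ier3, Igfbp3, Ddit4, Krt19 and Sparcl1. The call was lost for 26, 22 or 16 genes without double heterozygous replicate 1, 2 or 3, for 12, 13 or 12 without control replicate 1, 2 or 3, and for 4, 2, 0, 11 or 17 without CKO replicate 1, 2, 3, 4 or 5. Of 18193 genes 9.1% had groups that did not overlap, against 3.57% by chance.

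Cell cycle and metabolic lists moved in the same direction as against control. All 23 DNA replication genes had lower means (mean log2 fold change -0.33), 1 was called and 20 passed when adjusted over the list alone (camera adjusted p = 1.04e-14, and adjusted p = 0.0326 with an estimated correlation). Pcna was called (-0.39, SE 0.072, adjusted p = 0.0284), and Mcm7 (-0.43), Mcm4 (-0.28) and Gins1 (-0.43) were not. Of 24 G2-M genes 23 had lower means (mean -0.26), with Kif20a called (-0.59, SE 0.11, adjusted p = 0.0336) and 15 passing when adjusted over the list alone (camera adjusted p = 1.02e-13, and adjusted p = 0.0492 with an estimated correlation). The calls of Pcna and Kif20a were lost in 12 and 13 of 26 alternatives, on the deposited scale among them. Cdc20 (-0.43), Aurka (-0.40) and Ube2c (-0.40) did not pass. Ccnd2 was the 1 called member of the G1-S list (mean -0.10, camera adjusted p = 0.0454, and adjusted p = 0.143 with an estimated correlation), with Mycn at -0.25. It lost its call without control replicate 1 (-0.10), 2 (-0.10) or 3 (-0.10), double heterozygous replicate 1 (-0.11) or 3 (-0.097), or CKO replicate 1 (-0.093), 2 (-0.10) or 3 (-0.079). All 8 CDK inhibitors had higher means (mean 0.22) and 0 were called, with Cdkn1b at 0.49, Cdkn2a at 0.37 and Cdkn1a at 0.30 (camera adjusted p = 0.0183, and adjusted p = 0.105 with an estimated correlation). Cdkn2a was dim (4.104 to 4.608 in double heterozygous and 4.502 to 5.084 in CKO-labelled arrays), so its value depends on the offset. The CDK inhibitor list also passed with fry (adjusted p = 0.00888). The call with camera was lost without double heterozygous replicate 3 (0.19), on the deposited scale (0.17), with median centring (0.12) and as the mean of each gene's probe sets (0.14), and Cdkn1c, at 0.11, changed sign with median centring. All 18 hypoxia and glycolysis genes had higher means (mean 0.57), 5 were called and 13 passed when adjusted over the list alone (camera adjusted p = 3.39e-18, and adjusted p = 0.0492 with an estimated correlation). The called genes were Ddit4, Egln3, Bnip3 (0.74, SE 0.096), Higd1a (0.53, SE 0.079) and, named after its value was seen, Hk2 (0.64). On the deposited scale and with median centring Bnip3, Higd1a and Hk2 lost their calls, Hk2 in 12 of 26 alternatives overall. The 3 double heterozygous arrays scored between 0.054 and 0.075 on this list, below all 5 CKO-labelled arrays. Oxidative metabolism had a mean of -0.14 and 0 of 20 called (camera adjusted p = 5.61e-04, and adjusted p = 0.105 with an estimated correlation). Ndufs1 was at -0.34 and Idh3a at -0.40. The means were -0.38 (G2-M), -0.20 (G1-S) and -0.26 (oxidative metabolism) on the deposited scale, and -0.43, -0.25 and -0.30 with median centring. Chac1, a glutathione-degrading enzyme of amino acid stress, rose (1.33, SE 0.26, adjusted p = 0.0394) within a list that was not called (mean 0.16, camera adjusted p = 0.301), and its call was lost in 13 of 25 alternatives (2.49 with an offset of 1 and 0.62 with 64).

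Of the heart and cell type lists, Isl1 (0.69, SE 0.13, adjusted p = 0.0308) and 1 of 2 probe sets of Sema3c, a semaphorin of the outflow tract (0.51, SE 0.098, adjusted p = 0.0393), were called higher among 19 second heart field genes (mean 0.12, camera adjusted p = 0.00930, adjusted p = 0.351 with an estimated correlation and 0.172 with fry). The other Sema3c probe set was lower, the mean of both was 0.18, and the call was lost in 16 of 26 alternatives, among them each fit without 1 control or double heterozygous array. That of Isl1 was lost in 12. On the second heart field list 4 of 5 CKO-labelled arrays scored above all double heterozygous arrays, and CKO replicate 3 (0.016) scored below all of them. Kdr rose (0.68, SE 0.12, adjusted p = 0.0177) among endothelial genes (mean 0.18, camera adjusted p = 8.39e-04, and adjusted p = 0.0626 with an estimated correlation), with Cdh5 at 0.58 and Flt1 at 0.63, and the Kdr call was lost in 8 of 26 alternatives, both other scalings among them. Hapln1 (-0.56, SE 0.086, adjusted p = 0.00972), Has2, the hyaluronan synthase of the cardiac jelly (-0.52, SE 0.10, adjusted p = 0.0431), and Col2a1 (-0.49, SE 0.099, adjusted p just under the threshold) fell and Vcan rose (0.38, SE 0.066, adjusted p = 0.0215) in the cushion list. Its mean was lower (mean -0.23, camera adjusted p = 0.00601, and adjusted p = 0.351 with an estimated correlation), and the call was lost without double heterozygous replicate 3 (-0.18), without CKO replicates 2 and 3 together (-0.13) and with fry (adjusted p = 0.0903). For Vcan 7 of 8 probe sets were higher. The calls were lost in 7 of 26 alternatives for Hapln1, 11 for Vcan (0.21 with median centring and 0.22 as the mean of its probe sets), 13 for Has2 and 17 for Col2a1. The calls of the second heart field and endothelial lists were lost on the deposited scale (0.063 and 0.088) and with median centring (0.015 and 0.040). Krt19 was the 1 called member of the proepicardial list, whose members lay on both sides (4 higher and 8 lower, mean -0.08, camera adjusted p = 0.992). Wt1, an epicardial transcription factor, was at 0.64, Lrrn4 at -0.66 and Tcf21 at -0.70, none of them called. On the probe sets that represent the genes, Krt8 (0.53, SE 0.10, adjusted p = 0.0394) was the 1 called member of the pharyngeal endoderm list (mean 0.04, camera adjusted p = 0.187). Its call was lost in 12 of 26 alternatives. With 0 members called, camera adjusted p was 0.771 for cardiac transcription factors, 0.606 for sarcomere, 0.0978 for calcium handling, 0.227 for chamber, 0.561 for BMP signalling, and 0.998 for p53 response. It was 0.508 for smooth muscle, 0.0960 for erythroid, 0.195 for platelet and myeloid, 0.643 for liver bud, 0.627 for neural crest, 0.852 for neural tube, 0.195 for immediate early and 0.336 for sex-linked genes. Described GATA4 targets had Ccnd2 as the 1 called member (camera adjusted p = 0.788). Median and mean differed in sign for the cardiac transcription factor, BMP, pharyngeal endoderm and liver bud lists, and the camera direction of the p53 list differed from both. The count of 157 was 15, 35 or 78 without double heterozygous replicate 1, 2 or 3, 101 without control replicate 2, 71 without CKO replicate 5, 250 without CKO replicate 1, 415 without CKO replicate 3 and 650 without CKO replicates 2 and 3 together. The share of calls that were higher was 82.2%, against 66.2% of 65 with median centring.

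The calls of both comparisons overlapped: 116 probe sets were higher and 25 lower in CKO-labelled arrays against each of the other groups, and 0 moved in opposite directions. These comparisons share the CKO-labelled arrays. Independent lists of these sizes would share 1.08 higher and 0.159 lower probe sets, and the top-ranked lists of these sizes in unchanged simulated groups that share these arrays had means of 20.8 higher and 6.6 lower in common over 20 simulations. The first value leaves out the shared arrays and the second the effects. With the 5 CKO-labelled arrays split into 2 for one comparison and 3 for the other, in all 10 ways, a median of 61 probe sets (30 to 114) was called in both in the same direction.

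**Figure D3:**
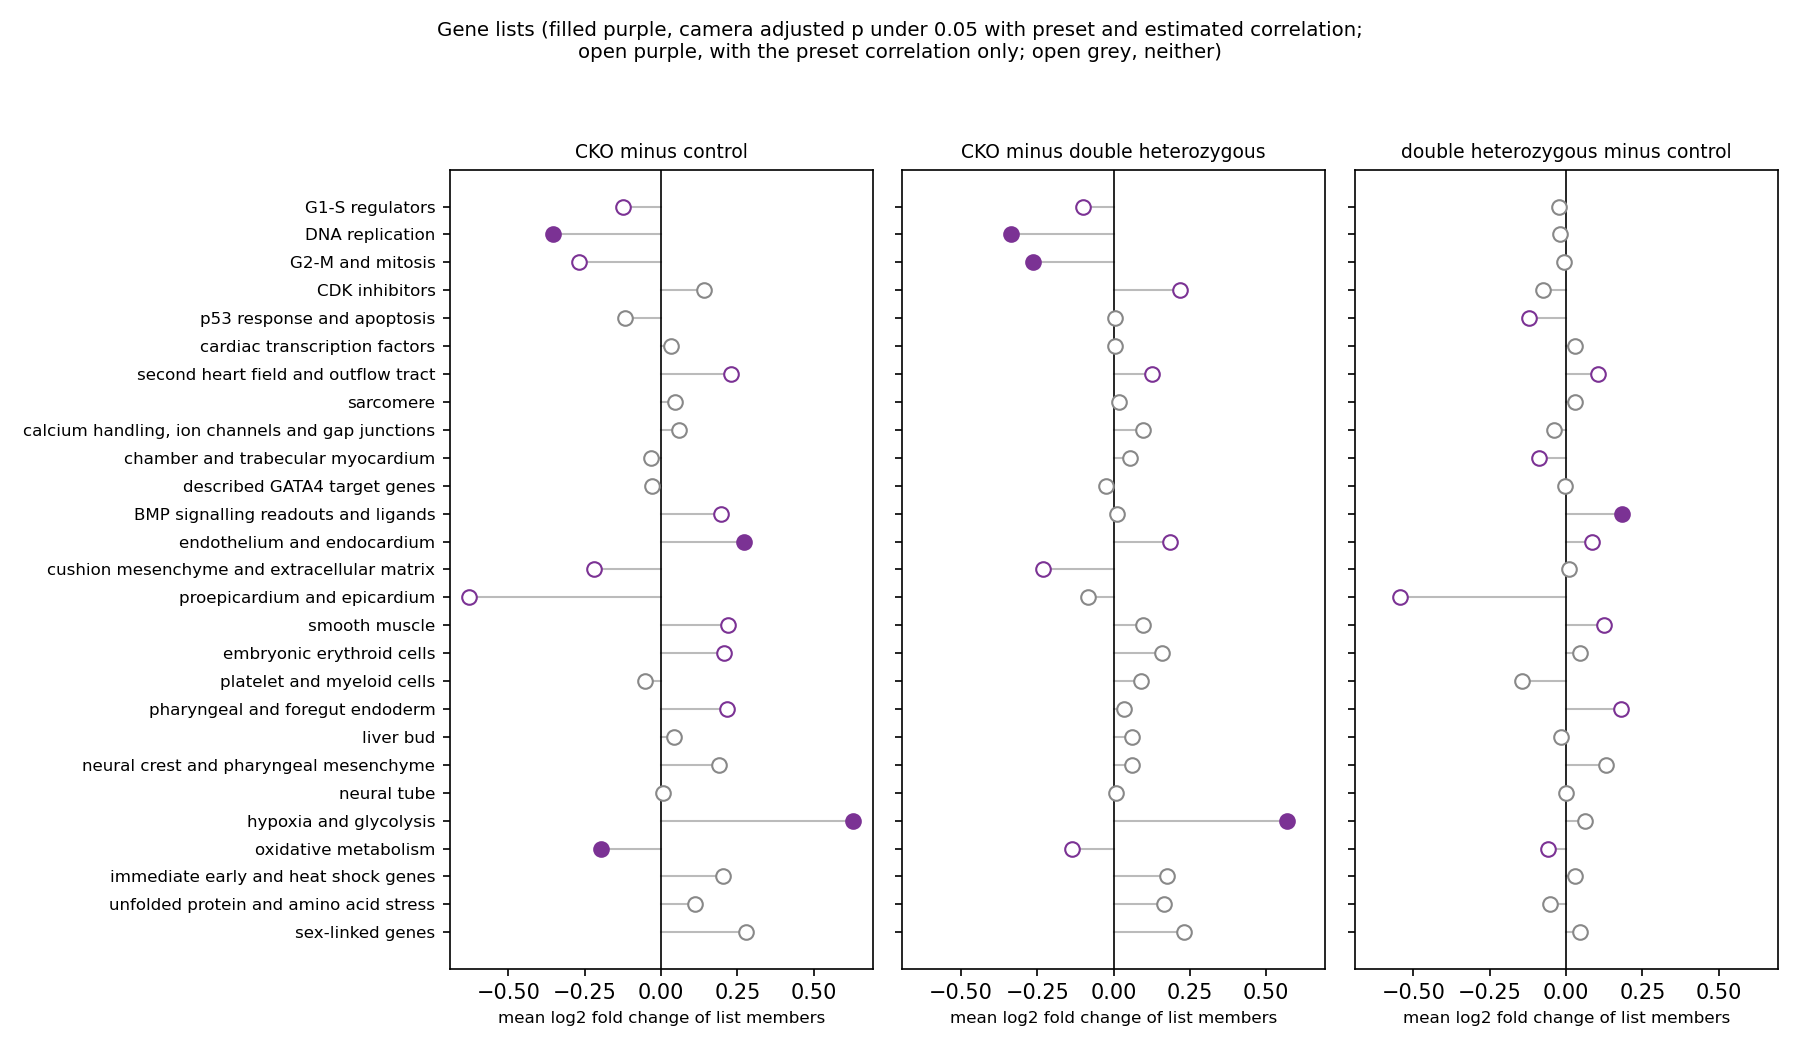
Mean log2 fold change of the members of each of the 27 gene lists in the 3 pairwise comparisons. Hypoxia and glycolysis (0.63 and 0.57) and DNA replication (-0.36 and -0.33) pass with both correlations in both comparisons with CKO-labelled arrays, and proepicardium and epicardium (-0.63 and -0.54) is low in both groups with Cre against control with the preset correlation only.

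The comparison of double heterozygous with control arrays asks what differs with Cre at 1 Nkx2-5 allele, which can also recombine the floxed Gata4 allele. BMP signalling genes were higher in double heterozygous arrays: 12 of 14 had higher means (mean log2 fold change 0.18), and 0 were called over all probe sets and 3 when adjusted over the list alone. All 3 double heterozygous arrays scored above all 3 control arrays (camera adjusted p = 1.52e-07, and adjusted p = 0.0326 with an estimated correlation). Bmp4, a ligand, was at 0.50 (SE 0.13), Id1 at 0.36 (SE 0.096), Msx2 at 0.35 (SE 0.14) and Bambi at 0.24 (SE 0.082), each with adjusted p = 1. Proepicardial and epicardial genes were lower, with 11 of 12 means lower (mean -0.54), 0 called, 3 passing when adjusted over the list alone and all 3 arrays below all control arrays (camera adjusted p = 1.07e-10, and adjusted p = 0.0977 with an estimated correlation). The mean was -0.34 with an offset of 64. Aldh1a1 was at -1.22 (SE 0.31), Upk1b at -0.87 (SE 0.21), Upk3b at -0.77 (SE 0.30) and Msln at -0.41 (SE 0.15). Msln lay near the level of a deposited value of 0 in double heterozygous arrays (4.053 to 4.23), so its value depends on the offset.

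No probe set was called in limma between double heterozygous and control arrays (0 of 45037, smallest adjusted p = 0.0977), and 1435 had an unadjusted p under 0.05, where 2252 would be expected by chance. With no variance moderation the count was also 0. A count below chance does not show that the groups are alike. The fit pooled their spread with that of the CKO-labelled arrays, which were less alike. Some other fits called a few probe sets, as given in the closing part. The smallest p-values among named genes belonged to Cck, the peptide cholecystokinin (0.89, adjusted p = 0.228), Itga6, an integrin subunit (0.45, adjusted p = 0.345), and Cfc1, a co-receptor for Nodal (0.71, adjusted p = 0.621), on the higher side. On the lower side they belonged to Reep2 (-0.90, adjusted p = 0.345), Rspo1, a Wnt pathway activator (-0.87, adjusted p = 0.345), and F13a1, a coagulation factor subunit (-0.72, adjusted p = 1). None of these passed. In double heterozygous arrays Reep2 (4.235 to 4.617), Rspo1 (4.082 to 4.433) and F13a1 (4.059 to 4.383) lay near 4.0, the level of a deposited value of 0. Their log2 fold changes therefore depend on the offset. Ccnd2 differed by -0.02 (SE 0.10, adjusted p = 1), and Gata4 by 0.33 (SE 0.11, adjusted p = 1). Isl1 was at 0.69 (SE 0.14, adjusted p = 0.687). Of 18193 genes 10.9% had groups that did not overlap, against 10% by chance for 3 against 3 arrays.

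Other lists that passed with the preset correlation in double heterozygous arrays did not pass with an estimated one. They were second heart field (mean 0.10, camera adjusted p = 0.0419, and adjusted p = 0.455 with an estimated correlation), endothelium (0.09, 0.0425 and 0.223), smooth muscle (0.12, 0.0149 and 0.105) and pharyngeal endoderm (0.18, 0.00601 and 0.351) on the higher side. On the lower side they were p53 response (-0.12, 0.0243 and 0.427), chamber (-0.09, 0.0167 and 0.0977) and oxidative metabolism (-0.06, 0.0234 and 0.298). With fry BMP signalling passed (adjusted p = 0.0153), while the proepicardial list (adjusted p = 0.130) and these 7 lists (0.172 to 0.541) did not. Each of these 7 calls was also lost without single arrays. For second heart field it was lost without control replicate 1 (0.089) or 2 (0.095), double heterozygous replicate 1 (0.11) or 3 (0.067), or CKO replicate 2 (0.10) or 4 (0.10). For endothelium the call was lost without control replicate 1 (0.064) or 2 (0.083) or double heterozygous replicate 1 (0.072), 2 (0.084) or 3 (0.10). That of smooth muscle was lost without control replicate 1 (0.11) or 2 (0.11) or double heterozygous replicate 1 (0.10) or 3 (0.096), and that of pharyngeal endoderm without control replicate 2 (0.13) or double heterozygous replicate 1 (0.12) or 3 (0.069), while its mean was 0.35 without double heterozygous replicate 2. It was lost for p53 response without control replicate 1 (-0.10) or 2 (-0.11) or double heterozygous replicate 1 (-0.11) or 3 (-0.073). That of chamber genes was lost without control replicate 3 (-0.052) or double heterozygous replicate 3 (-0.073), and that of oxidative metabolism without control replicate 3 (-0.040) or double heterozygous replicate 1 (-0.057) or 3 (-0.042). Cell cycle lists had means near 0, at -0.02 for DNA replication (camera adjusted p = 0.683), -0.01 for G2-M (0.923), -0.02 for G1-S (0.627) and -0.08 for CDK inhibitors (0.349), and hypoxia and glycolysis had a mean of 0.06 (0.0986). The remaining lists had camera adjusted p-values of 0.404 (cardiac transcription factors), 0.195 (sarcomere), 0.823 (calcium handling), 0.998 (described GATA4 targets), 0.923 (cushion), 0.534 (erythroid), 0.0808 (platelet and myeloid), 0.824 (liver bud), 0.186 (neural crest), 0.854 (neural tube), 0.493 (immediate early), 0.825 (unfolded protein) and 0.757 (sex-linked). The signs of small means such as these changed with scaling for G2-M, sarcomere, described GATA4 targets, cushion, neural tube, immediate early and sex-linked genes. Median and mean differed in sign for DNA replication, calcium handling and cushion genes. Of the 31 list results called with the preset correlation over the 3 comparisons, 8 were also called with an estimated one.

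**Figure D4:**
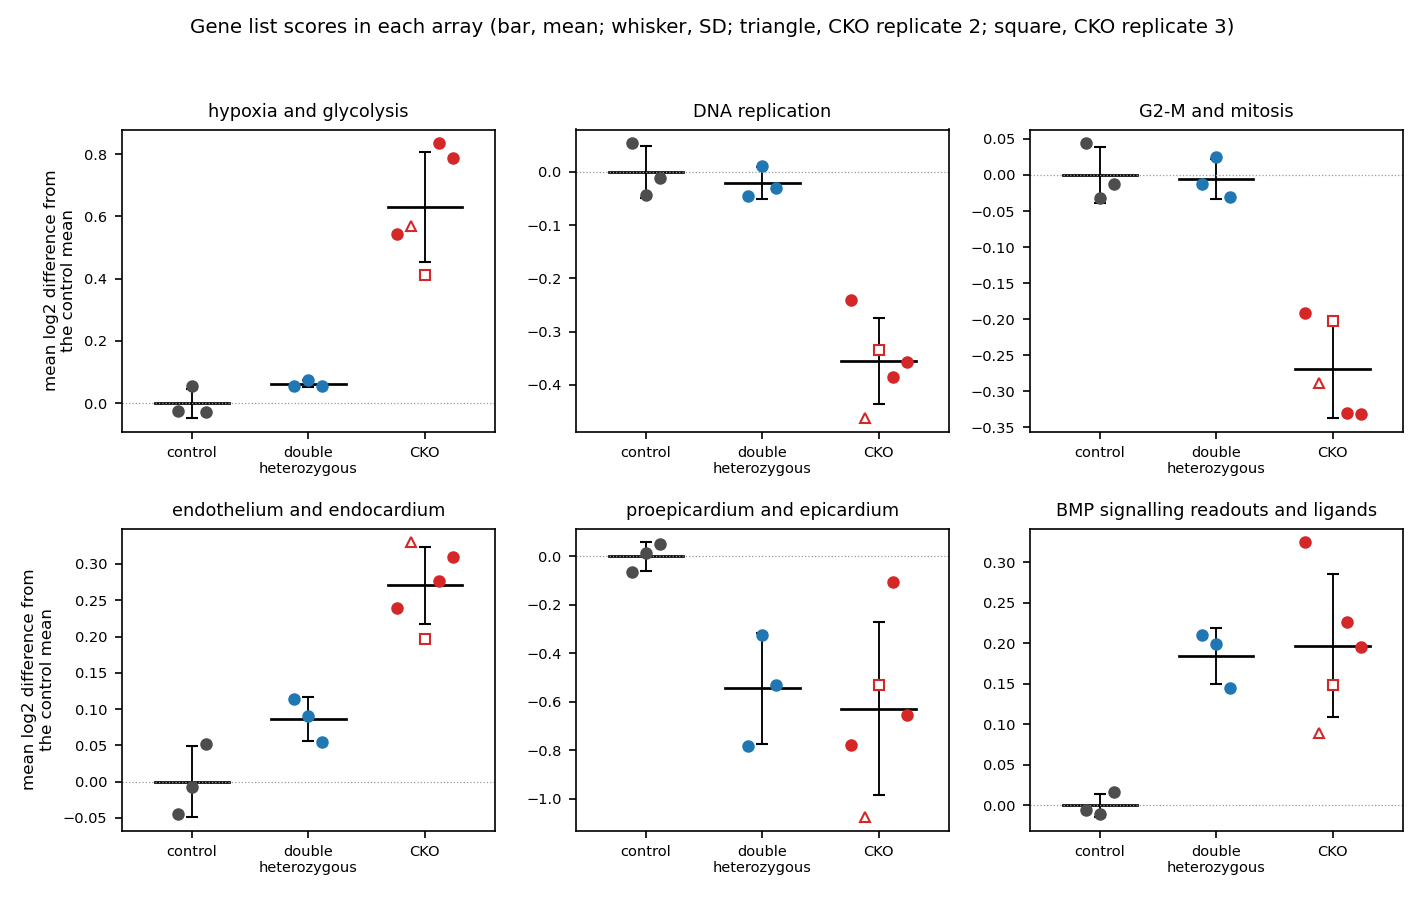
Score of 6 gene lists in each array, as the mean log2 difference of the list's members from their control mean, with 1 point per array, the group mean as a bar and the SD as a whisker; y axes differ between panels. On the hypoxia and glycolysis list the 5 CKO-labelled arrays lie between 0.41 and 0.84, above the other 6 arrays, and on the proepicardial list CKO replicate 4 (-0.10) lies nearest to the control arrays.

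Across the 3 genotypes the moderated F-test called 433 probe sets on 337 named genes. It called 185, 190 or 194 without control replicate 1, 2 or 3, 243 or 265 without double heterozygous replicate 1 or 2, 200 without CKO replicate 5, 653 without CKO replicate 3 and 885 without CKO replicates 2 and 3 together. Whether double heterozygous arrays lay away from the midpoint of the other groups was tested directly in limma. For this 0 probe sets were called (smallest adjusted p = 0.188), with 2074 at an unadjusted p under 0.05 against 2252 expected by chance, and 0 with no variance moderation. Shifts of CKO-labelled and of double heterozygous arrays from the same control arrays correlated across probe sets (r = 0.43, probe sets not being independent), where unchanged groups sharing these controls gave 0.56. The covariance was 0.0182 against 0.0213 in the simulation. With 3 control arrays no split was possible that kept 2 in each part.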

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

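No test in this part was chosen only after its result was seen. In groups of 5 arrays, a value was marked where its gap to the nearest of the others exceeded 0.71 of the group's range, which chance gives in about 1 in 20 groups. Of 103 items tested in the CKO-labelled arrays 12 exceeded it, where 5.15 would by chance, and they fell on CKO replicate 2 (5 items), CKO replicate 3 (3) and CKO replicate 4 (4).

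In CKO replicate 2, Ccnd2 read 11.48 against 11.03 to 11.14 in the other CKO-labelled arrays, the sarcomere list scored 0.187 against -0.008 to 0.041, and the list of described GATA4 targets, which includes Ccnd2, scored 0.052 against -0.069 to -0.035. The same array had a beta-actin 3' to 5' difference of 1.0 against 0.32 to 0.44 and a Gapdh difference of 0.35 against -0.139 to -0.00716. In CKO replicate 3, Mlip, a muscle gene, read 8.102 against 7.06 to 7.324, the second heart field list scored 0.016 against 0.253 to 0.305, and the mean deposited intensity was 117.2 against 170.4 to 175.1. In CKO replicate 4, Aldh1a1 read 5.445 against 4.022 to 4.232, Lemd1 4.257 against 4.0 to 4.056 (both genes at or near the level of a deposited value of 0 in the other arrays), Cfc1, a Nodal co-receptor, 6.876 against 7.197 to 7.221, and the liver bud list scored 0.291 against -0.055 to 0.031.

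Ccnd2 near the control level in CKO replicate 2 was weighed further, because Ccnd2 is the gene the study asks about. If a control or double heterozygous pool had been labelled CKO replicate 2, its other called genes would lie near control too. Over the 884 probe sets called without that array, its median position was 0.947 on an axis from control (0) to the other CKO-labelled arrays (1), which argues against such a label, and the other CKO-labelled arrays took positions from 0.639 to 1.09. RNA quality may have moved single probe sets apart: over 1195 genes, the median range between probe sets of 1 gene was 0.279 in this array and 0.113 to 0.226 in the others, the largest of the 5 but short of the margin set for a decision, and on the dimmest of the Ccnd2 probe sets this array was the lowest at 4.447. Variation of Ccnd2 between pools of CKO-labelled hearts was not tested and stays open.

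Other splits of the same arrays were fitted in the same way. Of the 56 splits of CKO-labelled and control arrays into groups of 5 and 3, 2 gave as many called probe sets as the real one, itself included (632, and 691 at the highest other). Of the 56 splits of CKO-labelled and double heterozygous arrays also 2 did (157, and 723 at the highest other). These shares are under 0.05, unadjusted for the number of split tests. In each, however, a split across the labels called more probe sets than the real one, so the counts do not exclude chance. The highest other split in each set CKO replicates 2, 4 and 5 against CKO replicates 1 and 3 together with the remaining group. In the second comparison it called several times the real count, which points to a structure among the CKO-labelled arrays. For the gene lists, the real split alone gave as large a mean shift (1 of 56) for hypoxia and glycolysis (0.63 against control, highest other 0.54, and 0.568 against double heterozygous, highest other 0.503), DNA replication (0.356 and 0.287, and 0.335 and 0.274) and G2-M (0.269 and 0.238, and 0.263 and 0.234), and 2 of 56 did for G1-S regulators (0.124 and 0.134, and 0.101 and 0.121). The real split was thus the most extreme for hypoxia and glycolysis, DNA replication and G2-M, but not for G1-S regulators. For the F-test 2 of 100 splits, the real one included, gave as many calls (433, highest other 935), so here too another split called more. For the midpoint the real count was 0 (highest other 3), so 100 of 100 splits had to give as many and the splits test nothing. The 10 splits of double heterozygous and control arrays are too few for a share under 0.05 (0, highest other 0, in 10 of 10).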

How the results depend on the processing

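The fit without CKO replicates 2 and 3 and the fit with the beta-actin 3' to 5' difference as a covariate were chosen after seeing the data. Of 90 called results for named genes 16 kept their call in every alternative run and 0 reversed. Counting each named gene under each alternative, apart from Ccnd2 in the comparisons with CKO-labelled arrays, a call was lost 592 times and gained 173 times and the side of the threshold stayed 6167 times; for lists not given singly these counts were 114, 34 and 1820. Of the 31 called list results 8 kept their call with an estimated correlation. Detection calls were not used here, so signal over background is unknown for dim probe sets, and a change there can be understated or missed. Another scaling moved the median of all probe sets by -0.0453 at most (in size). This median does not stand for the listed genes. In CKO-labelled against control arrays, the list means given in the Results for these scalings moved further, all towards lower values.

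Between CKO-labelled and control arrays the count of called probe sets was 92 on the deposited scale, 362 with median centring, 990 without the dimmest 60% of probe sets, 281 with no variance trend, 296 with no variance moderation, 2393 with array weights, 263 with only the groups compared in the fit and 1362 without CKO replicates 2 and 3; without each array in turn it was 168 to 897. Between CKO-labelled and double heterozygous arrays it was, in the same order, 15, 65, 269, 53, 1, 613, 61 and 650, and 15 to 415 without each array. Across the 3 genotypes it was 81, 284, 702, 198, 122 and 1599 for the first 6 of these, 885 without CKO replicates 2 and 3, and 185 to 653 without each array. Between double heterozygous and control arrays it was 8 with array weights, 1 with only the groups compared, 2 without CKO replicates 2 and 3 and 2 with the covariate. Off the midpoint it was 8 with array weights, 1 with the mean of the probe sets of a gene and 5 without CKO replicates 2 and 3. The filter tests fewer probe sets and the smaller fits hold fewer arrays, and otherwise the cause was not tested.

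Ccnd2 lost its call against control on the deposited scale (-0.6282), with no variance trend or moderation (-0.478) and with only the groups compared (-0.4775), and its values without each array lay between -0.5607 and -0.4488. Against double heterozygous arrays it lost its call with an offset of 1 (-0.4638) or 64 (-0.4527), on the deposited scale (-0.5846), with median centring (-0.6321), with no variance trend or moderation (-0.4611) and with only the groups compared (-0.4624), and lay between -0.5456 and -0.3916 without each array. The G1-S list lost its call against control without the dimmest 40% (-0.1241) or 60% (-0.119), with no variance trend (-0.1241), with array weights (-0.105), without CKO replicates 2 and 3 (-0.09793) and with an estimated correlation (-0.1241), with values of -0.1398 to -0.1012 without each array. Against double heterozygous arrays it did so in the same settings (-0.1014, -0.1094, -0.1014, -0.08131, -0.07517 and -0.1014), with the mean of probe sets (-0.101) and with only the groups compared (-0.1014), with values of -0.1171 to -0.0785 without each array. The G2-M list lost its call against control with an estimated correlation (-0.269). The cause was not tested. The DNA replication and hypoxia lists kept their calls and direction in all 27 alternatives in both comparisons (-0.3853 to -0.3075 and 0.5179 to 0.6836 without each array), as did G2-M against double heterozygous arrays.

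Same-numbered arrays deviated together weakly at most (9 pairs, r from -0.0557 to 0.15, 1 of them over 0.1), and not every array correlated best with its own number. With so few arrays per group, this neither shows nor excludes that the replicate numbers pair the samples. With the replicate block 265 probe sets were called against control, 65 against double heterozygous arrays, 157 across the 3 genotypes and 1 off the midpoint, and Ccnd2 stood at -0.4073 and -0.3904 and was not called.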

Other observations

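The hypoxia, proepicardium and chromosome neighbour tests in this part, and the Meg3, Dlk1, Rian and Mirg genes and the lists of keratins and of further hypoxia-responsive genes were chosen only after the results were seen.

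The maternally expressed long noncoding RNA Meg3 was higher in CKO-labelled than in control arrays on all 11 of its probe sets, 10 of them called, with log2 fold changes from 0.43 to 1.47. Against double heterozygous arrays all 11 were also higher and 4 were called, and double heterozygous arrays lay above control arrays on all 11 with 0 called in limma. On the probe set that represents Meg3 in the gene tests the control arrays read 9.185 to 9.585, the double heterozygous arrays 9.949 to 9.986 and the CKO-labelled arrays 10.438 to 10.975. Rian and Mirg, noncoding RNAs of the same imprinted cluster, were higher against control on 4 of 4 and 2 of 2 probe sets, with 0 and 1 called. Of the paternally expressed Dlk1, a Notch ligand family gene, 1 of 2 probe sets was called higher (1.02). A list of 26 measured imprinted genes apart from Meg3 and Dlk1, planned before its result was seen, was not called as a group (mean 0.069, camera p of 0.106), with Mirg its 1 called member. Its positive mean rests on Rian and Mirg: without them the other 24 had a mean of -0.01 (SD between genes 0.33), 14 higher and 10 lower, a calculation added after the values were seen. A rise of imprinted genes outside the cluster is thus not shown, and members that go both ways do not exclude it.

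Of 6 keratins of simple and surface epithelia 4 were called higher against control in limma, Krt8, Krt18, Krt19 and Krt20 (mean 0.67), and 2 against double heterozygous arrays, Krt8 and Krt19 (mean 0.50). Double heterozygous arrays had a mean of 0.18 with 0 called. Since called keratins prompted the list, it cannot test the rise independently. A list of 29 further measured hypoxia-responsive genes, written after the first calls were seen and holding some of those genes, had 15 called higher against control, 13 against double heterozygous arrays and 0 between double heterozygous and control arrays, and it cannot test the rise independently.

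Hypoxia and glycolysis genes were higher in all 5 CKO-labelled arrays. Poor quality of CKO replicates 2 and 3 is argued against, since the mean shift without them was 0.7204, against 0.63 with all arrays. More erythroid cells are argued against only for the 3 CKO-labelled arrays whose erythroid score was within the control range, replicates 2, 3 and 5. Their lowest hypoxia score was 0.413, in replicate 3, against 0.075 for the highest control or double heterozygous array (control SD 0.0471). Replicates 2 and 3 are the arrays of doubtful quality, so otherwise this rests on replicate 5 alone (erythroid score 0.054, hypoxia score 0.788). CKO replicates 1 and 4 scored 0.539 and 0.504 on the erythroid list, so more erythroid cells stay open there. Longer handling before lysis cannot be told apart, because the immediate early and heat shock list had a mean shift of 0.204 without being called, a shift that leaves it open. On that list 4 of 5 CKO-labelled arrays scored above all control and all double heterozygous arrays, and CKO replicate 3 (-0.138) scored below them. The 5 arrays took the same order on it as on the hypoxia list, from CKO replicate 4 (0.43 and 0.835) down to replicate 3 (-0.138 and 0.413). Lower oxygen in the CKO-labelled hearts may also raise these genes and was not tested.

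Proepicardial and epicardial genes had lower means in both groups with Cre (-0.63 in CKO-labelled and -0.54 in double heterozygous arrays), but neither call held with an estimated correlation (adjusted p = 0.342 and 0.0977) or with fry (0.172 and 0.13), and Wt1, an epicardial marker, was at 0.23 against control in CKO-labelled arrays and at -0.41 in double heterozygous arrays, neither called. Dilution that lowers endothelial genes as much as proepicardial genes is argued against: the lowest endothelial minus proepicardial score among the arrays with Cre was 0.381, against 0.02 for the highest control array (SD 0.0205). The fall of the proepicardial score is itself part of this gap. A larger share of endothelial cells, or a rise of endothelial genes that hides dilution, would give the same gap, so other dilution stays open. The gap replaced a test on the endothelial score alone, whose margin of 0.055 over 0.052 was too small to decide. Fewer proepicardial cells in these pools cannot be told apart from lower expression per cell. The SD between the shifts of the 11 members other than keratins was 0.284 in double heterozygous and 0.584 in CKO-labelled arrays. The median SE was 0.246 and 0.22. The SD in double heterozygous arrays lies close to the SE, so it does not show an uneven fall. The rule asked for an SD no larger than the SE in both groups, which sampling error alone can break. The offset also makes shifts of dim members such as Aldh1a1 and Msln uneven, and other cells can also express some members. Evenness replaced a count of lower members (11 in double heterozygous and 10, all but Wt1, in CKO-labelled arrays), which only restated the pattern.

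Genes next to Gata4 or Nkx2-5 on the chromosome, 100 on each side, were tested for DNA of another strain around the engineered alleles. One-sided Fisher exact tests gave p = 0.393 for Gata4 neighbours against control arrays (5 of 200 called, 2.5% against 2.05% of other genes) and p = 0.278 against double heterozygous arrays (2 of 200, 1% against 0.513%), which neither shows nor excludes it there (adjusted p = 0.59 for both, over 3 tests). Neighbours of Nkx2-5 showed no higher rate than other genes against control arrays (2 of 200, 1% against 2.07%, Fisher exact p = 0.92).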
